A study of Mus musculus with 4 samples.

How the data were processed

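The binding of p53, a transcription factor that responds to DNA damage, was measured by chromatin immunoprecipitation followed by hybridisation to promoter microarrays (ChIP-chip). Per the labels' protocols, R1E mouse embryonic stem cells were kept for 8 h in medium with 1000 units/ml leukaemia inhibitory factor, either untreated or with 0.5 µM adriamycin, a drug that damages DNA. Cells were fixed, and sonicated chromatin was precipitated with 10 µg of a p53 antibody. Input and precipitated DNA were amplified by ligation-mediated PCR, input was labelled with Cy3 and precipitated (IP) DNA with Cy5. Dyes were not swapped. Each condition was hybridised once to each of 2 array designs that cover different chromosomes, giving 4 arrays and 1 array per condition and design. Each array was a slide of its own, so slide and condition cannot be told apart, and both arrays of a design were compared only with each other.

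Per the file headers, the scanner images were processed with Agilent Feature Extraction 10.1.1.1, and the deposited processed signals are intensities, background-subtracted and scaled by a linear dye factor per channel, with no lowess step. The deposited scanner files also hold the intensity of each spot as a median, its local background, a log10 ratio of IP over input and a p-value from the software's error model. That p-value covers technical error of a spot alone and was not used. The authors' deposited value table holds log2 ratios whose processing is not given in the sources used here. Set against the scanner values, all 230959 and 231586 filled values of design 1 and all 234020 and 234748 of design 2 equalled, within 1e-06, the log2 ratio of IP over input from background-subtracted spot medians. Scale and direction of the table are therefore known and it is not centred. Its medians were -0.94 (untreated) and -1.00 (adriamycin) on design 1, and -0.93 and -0.45 on design 2.

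The measure was log2 of processed IP over processed input signal, centred on each array's median, with no loess or quantile step. Control spots, probes without a position and spots with an outlier mark in either array of a design were left out, which kept 236817 probes on design 1 and 236686 on design 2. Probes were sorted by position, and each run of 3 neighbouring probes spanning at most 1000 bp made a window, 202535 and 203579 in all. A window was bound when its mean was at least 1 (2-fold over the array median) and at least 2 of its 3 probes were at least 1. Bound windows that overlapped or lay within 500 bp were merged into a region. The same rule with the sign turned gave depleted regions, a background count within each array. For the comparison, bound windows of both arrays of a design were merged, and the window with the highest mean over both arrays gave the difference, adriamycin minus untreated. Regions were called higher at 1 or more and lower at -1 or less.

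With 1 array per condition there was no test and no p-value, and the number of arrays limits the precision. Errors given with a region are standard deviations (SD) over the 3 probes of its window, which are not replicates. The noise of a single log ratio, taken from differences between neighbouring probes outside bound regions, was 0.69 (untreated) and 0.57 (adriamycin) on design 1, and 0.70 and 0.45 on design 2. A control probe with 480 spots per array had an SD of 0.23 and 0.29 on design 1, and of 0.16 on both arrays of design 2. Negative control spots lay at a median log2 ratio of 1.22 and 1.26 on design 1, and of 0.95 and 0.58 on design 2, so spots near background can reach the threshold of 1. In the untreated and adriamycin arrays, 98.8% and 99.0% of probes of design 1 and 98.9% and 99.6% of design 2 had an input signal well above background. For the IP signal the shares were 95.6% and 94.3% on design 1, and 97.3% and 98.2% on design 2. Median background-subtracted IP spot signals were low, 24.5 and 26.5 on design 1, and 37 and 65 on design 2. Median local IP backgrounds were 52 and 51, and 53 and 54.

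The region rule was tested on simulated arrays, with 50 sites of each kind per design. Their noise was normal and independent between probes and arrays, with an SD taken from differences between neighbouring probes. Of the sites raised from 0.5 to 3 on the log2 scale, 47 of 50 were called higher on each design, and of the sites lowered from 3 to 0.5, 49 were called lower on each. Of the unchanged sites, 1 of 50 was called higher and 3 of 50 lower on each design, and of the sites raised from 2 to 2.5, 6 (design 1) and 2 (design 2) of 50 were called higher. This simulated noise alone gave 904 regions on design 1 and 813 on design 2 at the threshold of 1. Of these, 490 and 588 counted as lower with adriamycin and 91 and 4 as higher, and at a threshold of 2 there were 0. Log ratios of the real arrays had SDs of 1.06 (untreated) and 0.94 (adriamycin) on design 1, and 1.08 and 0.91 on design 2. At a threshold of 2 they held 84 and 15 depleted regions on design 1, and 101 and 19 on design 2. The simulated counts therefore do not give the number of false regions in the real arrays.

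Settings, alternatives and the rule for named regions were fixed before the data were examined. Named were the 10 regions with the highest log2 ratio in the adriamycin arrays, the 10 with the largest rise and the 10 with the largest fall, leaving out windows with a saturated spot. Alternatives were normexp background correction, the deposited table, loess, centring on the mode, equal spread of both arrays, a filter on dim input, other thresholds, windows of 5 probes, medians of probes, means over whole regions, a smaller change and a stricter overlap. Normexp used spot medians. In 2 arrays, a few spots with extreme local background (up to 16173 and 17991, against medians of 51 and 53) pulled its fit off, and its log ratios then correlated at 0.45 and 0.50 with the processed ones, against 0.80 and 0.89 in the other arrays. A fit without such spots was added after this was seen, as were a common input, windows with like input, a correction for probe length and input signal, and a threshold of 2.

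Positions are given as the array files give them, 1-based, and their genome build is not given in the sources used here. The files pair no probe with a gene. The gene table at hand, of assembly GRCm38.p6, was checked by its start coordinates, taken without regard to strand, which makes the check a coarse one. Inside tiled regions lay 7.07% (design 1) and 7.27% (design 2) of them, and 6.98% and 6.80% after a shift of 100000 bp. The gene table was taken to be of another build and was not used. Regions are therefore named by position, and the 12 gene lists fixed beforehand, with the genes named with them, were not analysed here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 (normexp and loess) were used.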

Results

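The data set held 4 promoter arrays of p53 ChIP-chip in R1E cells, a line of mouse embryonic stem cells, and its stated goal was to find p53 binding sites without and with DNA damage by adriamycin. Design 1 tiled 8386 regions on chromosomes 1 to 8 and part of chromosome 9, and design 2 tiled 8160 regions on the rest of chromosome 9 and the other chromosomes. A tiled region had a median width of 7548 bp on design 1 and 7562.5 bp on design 2, with a probe about every 183 bp and 182 bp. Values are log2 ratios of IP over input relative to the array median, from 1 array per condition and design without replicates. Across 3-probe windows, untreated and adriamycin log ratios correlated with r = 0.71 on design 1 and 0.73 on design 2. Windows are not independent replicates.

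The first question was where p53 IP signal lay above input in each condition. Windows with a saturated spot were left out of the list of highest regions. The 10 regions highest with adriamycin among the rest were about as high without it. Their log2 ratios were 4.77 to 5.37 in the adriamycin arrays and 4.10 to 5.35 in the untreated arrays. The highest, on chromosome 14 from 33207541 to 33208462, reached 5.37 ± 0.40 (SD over 3 probes) with adriamycin and 4.93 ± 0.51 without. The next, on chromosome 15 from 85687008 to 85688027, reached 5.09 ± 0.54 and 4.79 ± 0.38. A region of 5162 bp on chromosome 17, from 28818276 to 28823437, reached 4.77 ± 0.75 with adriamycin and 5.14 ± 0.95 without. The regions on chromosome 6 from 140581905 to 140585664 and on chromosome 5 from 111051869 to 111054734 each reached 4.85 with adriamycin (± 0.75 and ± 0.58) and 4.72 ± 1.06 and 4.78 ± 0.72 without. On chromosome 7, the region from 102353227 to 102354764 had 4.81 ± 0.24 and 5.35 ± 0.50. The differences of these 10 regions ran from -0.53 to 0.67, none reaching the 2-fold rule. They are of 1 window per region, the highest over both arrays, so other parts of a region could differ more. In the chromosome 17 region, the probes at 28822856, 28823185 and 28823303 had -0.23, 0.17 and 0.32 untreated. With adriamycin these probes, chosen after their values were seen, had 1.13, 1.78 and 1.41.

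At the 2-fold rule, 8171 regions were bound in the untreated arrays (4011 on design 1 and 4160 on design 2) and 7251 in the adriamycin arrays (3501 and 3750). Of the adriamycin regions, 3957 (54.6%) shared at least 1 probe with an untreated region. The sign-turned background was of the same order, with 8399 depleted regions in the untreated and 5096 in the adriamycin arrays. At this rule, bound regions were thus not set apart from the spread of the arrays. Depleted regions thinned out quickly at higher thresholds. At a log2 ratio of 2, the untreated arrays had 947 bound and 84 depleted regions on design 1 and 1044 and 101 on design 2, and the adriamycin arrays had 999 and 15, and 1102 and 19. Holding depleted regions to 5% of bound ones put the threshold at 2.15 for the untreated and 1.8 for the adriamycin arrays, on both designs. This stricter rule left 1707 untreated and 2543 adriamycin regions, 1326 of the latter shared.

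**Figure D1:**
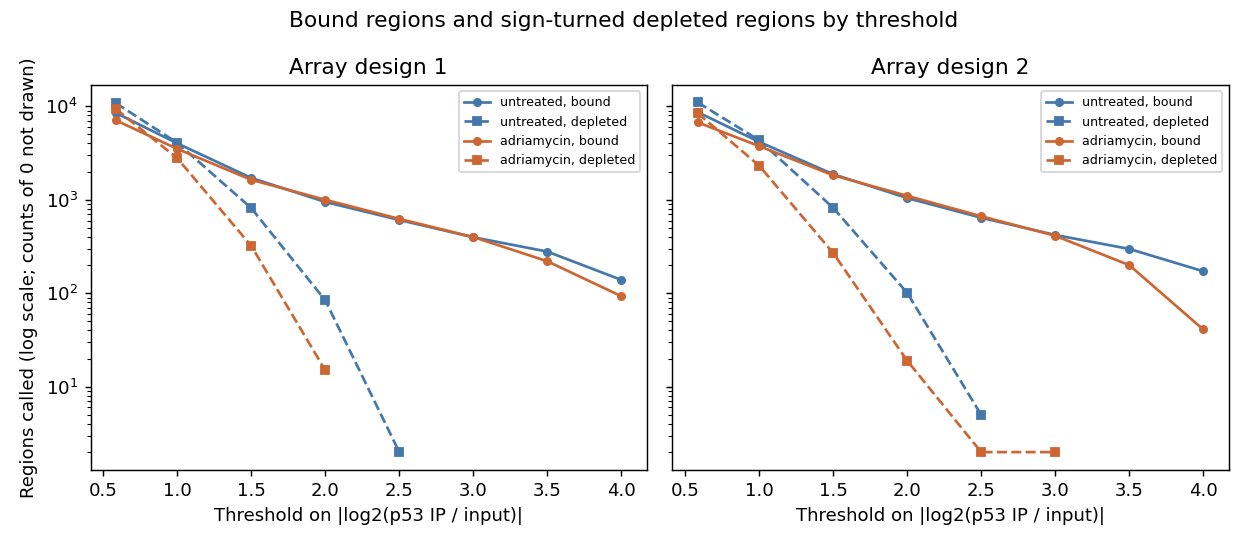
Number of bound (solid) and depleted (dashed) regions in each array by the threshold on the absolute log2 ratio of p53 IP over input, on a log scale, with a panel per array design. At a threshold of 1 depleted regions were 104% (untreated) and 61.8% (adriamycin) of bound ones on design 2, and at 2 they were 9.67% and 1.72%.

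The second question was which regions differed between conditions. The largest rise was on chromosome 13 from 54533026 to 54535152, from 0.53 ± 0.11 in the untreated to 3.84 ± 0.57 in the adriamycin array, 9.92-fold. On chromosome 19, the region from 6264508 to 6266463 went from 0.49 ± 0.36 to 3.54 ± 0.53 (8.27-fold). On chromosome 2, the region from 180220105 to 180221886 went from 1.13 ± 0.56 to 3.90 ± 0.30 (6.84-fold). All these values are of the best window alone. At the 2-fold rule, the regions on chromosomes 19 and 2 were also bound in the untreated array, elsewhere in the region. On chromosome 7, the region from 112160834 to 112162096 went from 0.12 ± 0.31 to 2.84 ± 0.79 (6.59-fold), but this difference of 2.72 was 0.90 with normexp, below the 2-fold rule, and 1.41 with normexp without extreme local backgrounds. In these 4 regions the IP signal alone, relative to its array median, was higher by 4.04, 3.90, 3.77 and 2.98 on the log2 scale, and the input by 0.77, 0.90, 0.99 and 0.25. On chromosome 1, the region from 46795732 to 46796543 went from 0.37 ± 0.19 to 2.91 ± 0.53 (5.83-fold), and on chromosome X, the region from 159417832 to 159418404 from 0.77 ± 0.85 to 3.33 ± 1.02 (5.90-fold). The difference on chromosome 1, 2.54, was 1.23 and 1.65 with the same 2 alternatives. With loess, the differences of the named regions on chromosomes 13, 19, 2 and X (159417832) were smaller, at 2.39, 2.15, 2.03 and 1.90. With a common input they were larger, at 4.05, 3.91, 3.74 and 2.96. With normexp they were 3.93, 3.71, 2.20 and 2.515, and without extreme local backgrounds 3.36, 3.13, 2.56 and 2.26. The normexp fit over all spots was pulled off in 1 array of each design. Of the 10 largest rises, with differences of 2.52 to 3.31, 7 passed the stricter rule and 2 held a spot not well above background. Those 2, on chromosome 6 from 116174861 to 116175531 and on chromosome 4 from 95456808 to 95457208, had differences of 2.95 and 2.57. Their IP signal alone changed by 0.66 and 0.15, and their input by -2.29 and -2.42. With a common input these 2 differences were 0.63 and 0.12, while 8 of the 10 rises kept 1 or more.

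**Figure D2:**
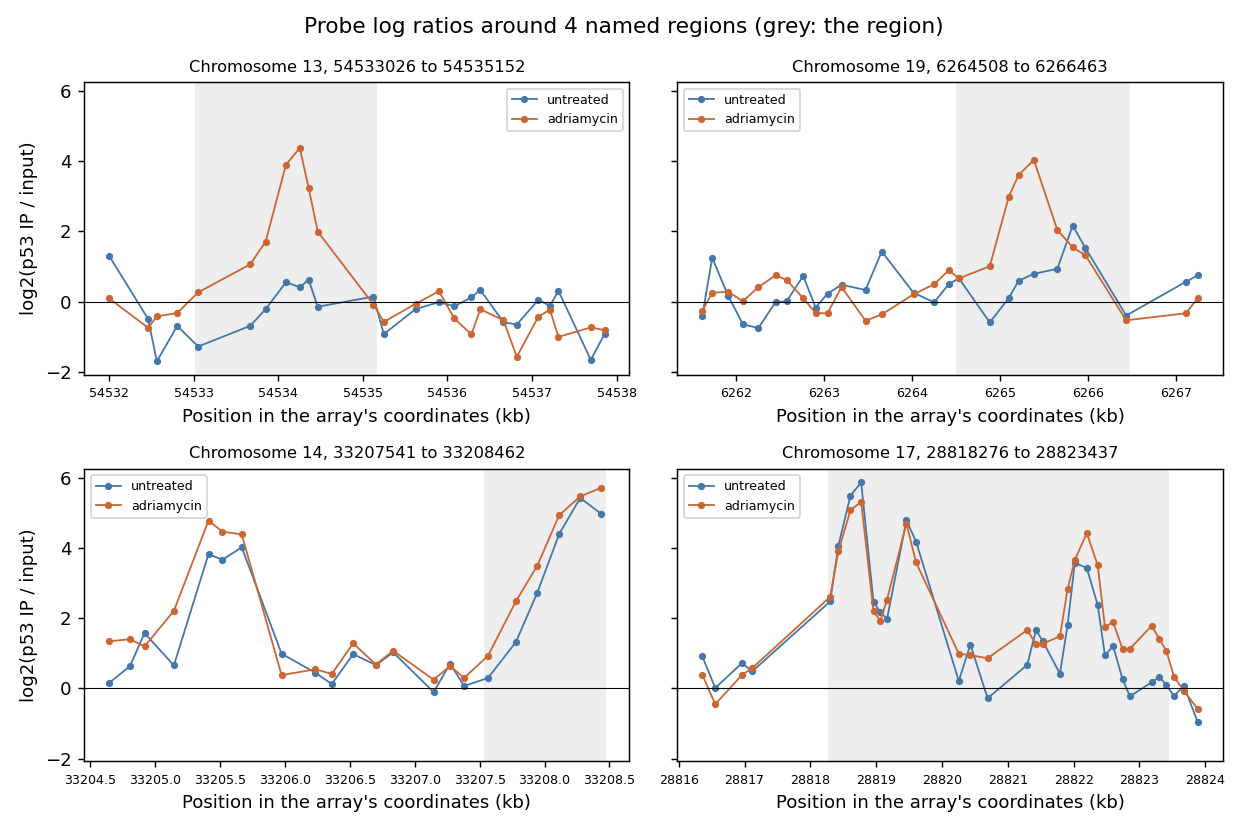
Probe log2 ratios of p53 IP over input (y axis) by position in the array's coordinates (x axis, kb) for the untreated and the adriamycin array, around 4 named regions shaded in grey. The regions on chromosomes 13 and 19 rose from 0.53 and 0.49 to 3.84 and 3.54 in their best windows, and those on chromosomes 14 and 17 differed by 0.44 and -0.38 in theirs.

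Regions with the largest falls had a dim input signal in the untreated array. Their differences ran from -3.99 to -3.50, and the input signal of all 10 was higher in the adriamycin array, by 0.94 to 3.07 on the log2 scale. Their IP signal alone changed by -2.72 to -0.42, and in 7 of the 10 by -1 or less. The IP changes of -2.72 and -1.94, both on chromosome 8, rest in part on an IP spot not well above background, so their sizes are uncertain. Among regions merged at the 2-fold rule, the largest fall was on chromosome X from 46130203 to 46131419, from 3.44 ± 1.12 to -0.55 ± 0.59, with an IP change of -1.83 and an untreated input at the 0.76th percentile of windows. On chromosome 8, the region from 47434490 to 47434855 had an IP change of -2.72 and an input change of 0.94. It held 1 IP spot not well above background, its difference had an SD of 2.63 over 3 probes, and it did not pass the stricter rule. On chromosome 9, the region from 15457365 to 15458326 went from 2.92 ± 1.49 to -0.58 ± 0.34, with input higher by 3.07. On chromosome 12, the region from 116924975 to 116925995 went from 3.60 ± 0.86 to -0.01 ± 0.56, while its IP signal alone fell by 0.58 and its input was higher by 3.07. In 5 of the 10 a spot was not well above background, and no fold is given for these falls. With normexp, 0 of the 10 kept a size of 1. Its offset of the signals shrinks ratios of dim spots by construction, and its fit was pulled off in 1 array of each design. The normexp values therefore do not decide how large these falls are. The stricter rule, which draws narrower regions, gave 2 larger falls on chromosome 19, chosen after their values were seen. The region from 12159229 to 12159591 went from 2.43 ± 0.46 to -1.91 ± 0.96 (difference -4.35), with an IP change of -2.27 and an input change of 2.12. None of its input spots was marked as not well above background. That mark does not show a bright input, as the fall on chromosome X from 46130203 had no such spot at the 0.76th percentile. The region from 34539136 to 34539666 went from 3.54 ± 1.65 to -0.54 ± 0.17 (-4.08), with an IP change of -0.72, an input change of 3.40 and 1 untreated input spot not well above background.

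At the 2-fold rule, 1319 of the 11210 merged regions were higher with adriamycin (11.8%; 682 on design 1 and 637 on design 2) and 2873 were lower (25.6%; 1386 and 1487). Among windows never bound, 3.84% and 3.43% were that much higher, and 4.84% and 4.67% that much lower. Merged depleted regions of the same rule gave shares close to those of bound regions: of 11549, 1328 (11.5%) were more and 2451 (21.2%) less depleted with adriamycin by at least 1. Which direction was the more frequent depended on the processing. Higher regions made up 31.5% of all changed regions in the main setting, 16.4% with loess, 55.3% with both arrays scaled to the same spread and 69.7% with the deposited table. With normexp it was 90.2%, but the designs went opposite ways, with 24 higher and 128 lower regions on design 1 and 1160 and 0 on design 2, and the fit was pulled off in 1 array of each design. Without extreme local backgrounds, normexp gave 143 higher and 15 lower regions on design 1, and 627 and 3 on design 2. At the stricter rule, whose threshold was lower for the adriamycin arrays, 635 regions were higher (319 and 316) and 319 lower (135 and 184). At an equal threshold of 2, 509 were higher and 432 lower. As a background, the same stricter thresholds with the sign turned gave 198 merged depleted regions, of which 85 (42.9%) were more and 68 (34.3%) less depleted with adriamycin by at least 1. Both shares were above those of the 2841 merged bound regions, 22.4% higher and 11.2% lower.

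**Figure D3:**
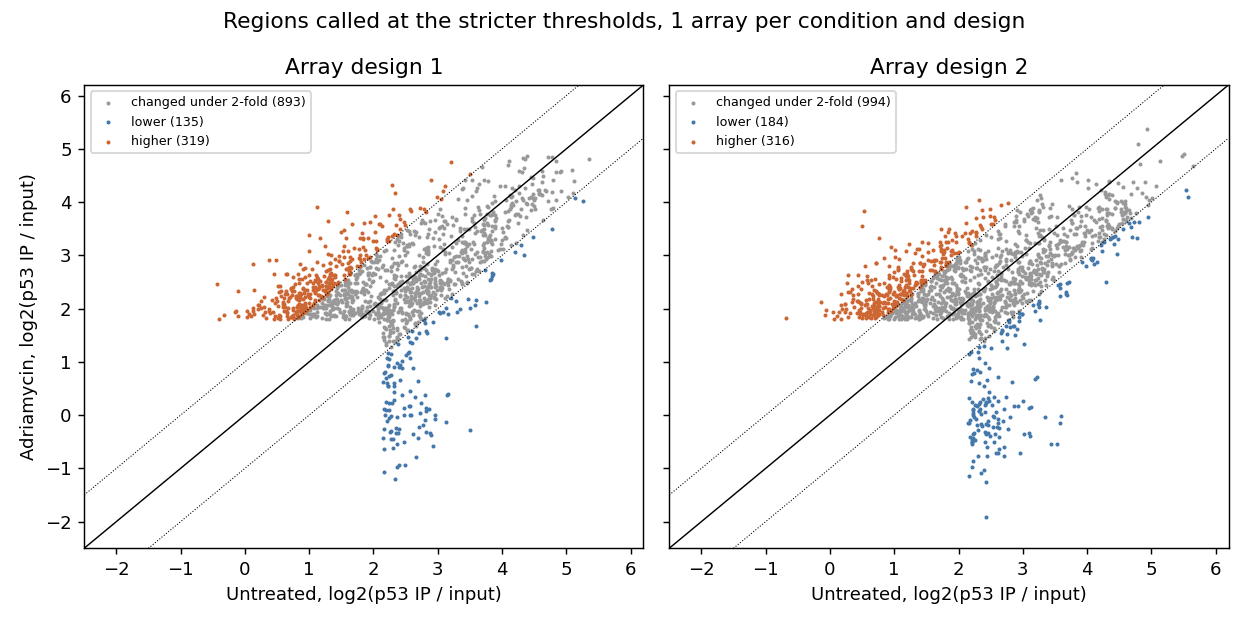
Log2 ratio of p53 IP over input in the untreated (x axis) and adriamycin array (y axis) for each region of the stricter rule, with a panel per array design, coloured by a difference of at least 1, with the diagonal solid and differences of 1 dotted. On design 1, 319 regions were higher and 135 lower, and on design 2, 316 and 184, and the straight lower and left edges are the thresholds of 1.8 and 2.15.

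Regions higher with adriamycin were mostly narrow, and narrow regions differed in both directions. In the stricter set, 526 (32.5%) of the 1619 regions up to 1000 bp wide were higher with adriamycin and 222 (13.7%) lower. Of the 635 regions between 1000 and 2000 bp, 106 (16.7%) were higher and 45 (7.09%) lower, and of the 132 regions wider than 5000 bp, 0 were higher and 12 (9.09%) lower. The lower threshold for the adriamycin arrays favours rises here, as 1200 regions were called in the adriamycin array alone and 322 in the untreated array alone. At an equal threshold of 2, 506 of the 2131 regions of at most 2000 bp were higher and 379 lower, and at the 2-fold rule 1232 of 9641 were higher and 2757 lower. At the 2-fold rule the narrowest regions did not have the highest share of rises, which was 11.4% up to 1000 bp, 16.9% from 1000 to 2000 bp and 9.47% from 2000 to 3000 bp. Of the regions of at least 3000 bp, 1 of 334 was higher and 32 were lower at a threshold of 2. The 632 higher regions of at most 2000 bp had a median difference of 1.34 (2.53-fold; interquartile range over regions 1.15 to 1.60), and their IP signal alone differed by a median of 1.49. The 306 regions of at least 3000 bp that were called in both arrays and changed under 2-fold had medians of 3.92 in the untreated and 3.54 in the adriamycin arrays. The width limits were chosen after the data were seen, and width rose with the log ratio itself. Log ratios of the adriamycin arrays had smaller SDs, 0.94 against 1.06 on design 1, and 0.91 against 1.08 on design 2. The shares by width are without scaling to the same spread, so the part of the spread in them was not tested.

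**Figure D4:**
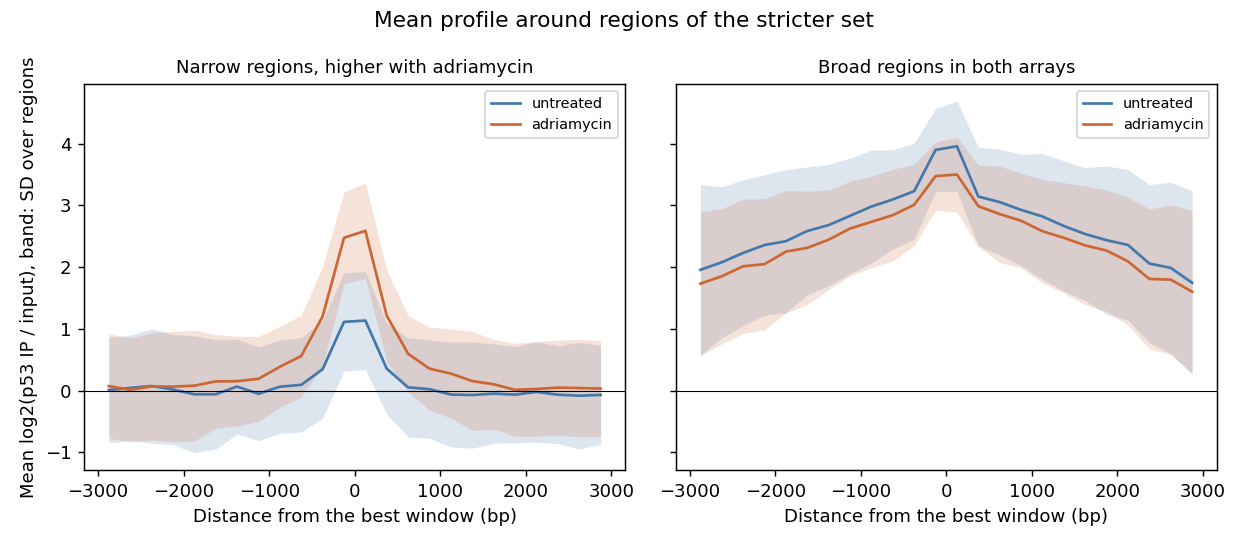
Mean log2 ratio of p53 IP over input (y axis; band, SD over regions) by distance from the best window (x axis, bp) for narrow regions higher with adriamycin and for broad regions called in both arrays. In the bin centred 125 bp from the best window, narrow regions averaged 1.13 untreated and 2.59 with adriamycin, and broad ones 3.96 and 3.50; at -1875 bp they averaged -0.06 and 0.08, and 2.42 and 2.25.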

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

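Normexp without extreme local backgrounds, the common input, the windows with like input, the correction for probe length and input, and the threshold of 2 were chosen after seeing the data. No named region changed sign in the 9 settings that change the values, except that 1 of the 10 falls had no value with the filter on dim input. The 10 highest regions stayed at 2.97 or more in each of these settings. The named falls shrank most: with a common input they ran from -2.75 to -0.46. With normexp, whose offset shrinks ratios of dim spots by construction, 0 of 10 reached a size of 1, and 1 did without extreme local backgrounds. With a common input 7 of the 10 falls did. All 10 did with the deposited table (-2.73 to -1.62) and with loess (-3.84 to -3.14). The same held with centring on the mode, equal spread and the correction for probe length and input, and for the 9 falls with a value under the filter on dim input. Of the 10 named rises, 8 kept a difference of at least 1 with a common input, 6 with normexp and 9 with the deposited table. The cause was not tested where none is given. Counts below are untreated bound, adriamycin bound, higher, lower and shared regions, as far as they moved by over 1.5 times. No paired analysis was possible because each condition had 1 array per design. Gene list values were not run, for want of gene names.

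Normexp gave 1482 untreated, 2787 adriamycin, 128 lower and 1162 shared regions, with correlations of 0.78 and 0.45 on designs 1 and 2, each with a fit that had been pulled off in 1 of its arrays, and noise of 0.26, 0.21, 0.37 and 0.22 (untreated and adriamycin of design 1, then design 2). Without extreme local backgrounds it gave 1892, 3162, 770 higher, 18 lower and 1668 shared, correlations of 0.83 and 0.78, and noise of 0.26, 0.23, 0.32 and 0.22; its offset of the signals shrinks ratios of dim spots by construction. The deposited table gave 548 lower regions and correlations of 0.76 and 0.80. Loess gave 4803 adriamycin and 734 higher regions, and correlations of 0.65 and 0.67. The equal spread gave 2505 higher regions. The filter on dim input gave correlations of 0.73 and 0.75. A common input gave 5382 untreated and 373 lower regions, and correlations of 0.76 and 0.79. Windows with like input gave 1249 lower regions, and the correction for probe length and input 1610.

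A threshold of 1.5-fold gave 17158 untreated, 13817 adriamycin, 4505 lower and 8441 shared regions. A threshold of 1.5 on the log2 scale gave 3589, 3462, 851 higher, 1138 lower and 2101 shared. A threshold of 2 gave 1991, 2101, 509, 432 and 1338, and the one set by depleted regions 1707, 2543, 635, 319 and 1326. Windows of 5 probes gave 4215, 4684, 555 higher and 860 lower. A change of 1.5-fold gave 2909 higher regions. Counts stayed within 1.5 times in 8 of 16 settings for untreated regions, 8 of 16 for adriamycin regions, 10 of 18 for higher, 7 of 18 for lower and 11 of 17 for shared ones. Leaving out probes with input near background left 2308 lower and 1241 higher regions.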

Other observations

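Mitochondrial DNA lay far below the array median and further below it after adriamycin. The 47 mitochondrial probes, all on design 2, had a median log2 ratio of -2.27 in the untreated array (interquartile range over probes -2.46 to -2.06) and of -2.87 with adriamycin (-3.02 to -2.73). Their input signal was very bright, with medians of 103747 and 91289 against 972 and 1163 over autosomal probes. On chromosome X, which lies on design 2 alone, 48 of the 125 regions of the stricter rule (38.4%) were lower with adriamycin. Over all 1494 regions of design 2, chromosome X among them, 184 (12.3%) were lower. The median input signal of chromosome X probes was 383 in the untreated and 441 in the adriamycin array, below the 972 and 1163 over autosomal probes.

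On chromosome 17, the neighbouring regions from 39451689 to 39454665 and from 39456527 to 39456882 had the brightest input of all regions of the stricter rule, 5.25 and 4.85 above the array median on the log2 scale in the untreated array. Their log2 ratios were 5.48 ± 0.20 and 5.52 ± 0.10 (SD over 3 probes) untreated, and 4.87 ± 0.22 and 4.91 ± 0.36 with adriamycin. They were chosen after their values were seen. Their adriamycin values lay within the range of the 10 highest regions named above. They are not among those 10, from which windows with a saturated spot were left out. Among probes without a position, 4 of 323 on design 1 and 9 of 415 on design 2 were at 8-fold or more in both arrays (1.24% and 2.17%, against 0.891% and 0.933% of all positioned probes).

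Of the tests that follow, those with a common input, of the probe length and input trend, of the IP channel alone, of many copies, of a single bright spot and of a slide blemish were chosen only after the result was seen. The filter on dim input was planned, but its bounds were set afterwards, and the patterns themselves were found in these data.

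More regions were lower than higher with adriamycin in the main setting, 2873 against 1319. Leaving out probes with input not well above background kept 2308 lower against 1241 higher regions, which argues against such spots as the whole cause. With the mean input of both arrays as a common denominator there were 373 lower and 1961 higher regions, and with both arrays scaled to the same spread 2024 and 2505, so a low untreated input above background or the larger spread of the untreated arrays may account for the excess, and the tests do not separate them. The IP signal alone changed by a median of -0.42 in the lower regions (interquartile range -0.77 to -0.09), which does not decide whether less p53 was precipitated there. A loss of binding stays open, and slide and condition cannot be told apart.

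Broad regions were enriched in both arrays. If they were sequence present in many copies, their input should be bright, but the median percentile of their input among windows was 71.7. The median log ratio of probes of like length and input made up a median of 8.23% of the log2 ratio of the 306 regions in the adriamycin arrays (interquartile range 3.28% to 14%), the higher of the conditions, and left medians of 3.78 untreated and 3.21 with adriamycin, which argues against that trend as the whole cause. Affinity of the antibody for something other than p53 was not tested, as no control precipitation was used here. That these are sites bound by p53 without damage is a hypothesis.

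In the stricter set, 632 of the 2254 regions of at most 2000 bp were higher with adriamycin and 267 lower, while depleted regions of the same thresholds, few as they were, changed in larger shares (42.9% more and 34.3% less depleted, of 198 regions of any width). With a common input, 85.3% of the 632 kept a difference of at least 1, which argues against a change of input. The probes next to their best windows, within 500 bp and outside them, differed by a median of 0.82 (interquartile range over 624 regions 0.44 to 1.21). The calling rule already asked for more than a single probe over the threshold, so a single bright spot could not make a region by itself. Neighbouring probes can lie inside the same called region, which was selected for high values. Their difference is therefore not a separate test of a single bright spot. In 0% did the 3 spots lie within 20 spots of each other on the slide, but the layout gave this for all but 5 of the 406114 windows, so a blemish was not tested by it. Gain of p53 binding at these sites after damage may be the cause, as a hypothesis, while a blemish and a difference between slides or precipitations stay open with 1 array per condition.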
